A study of Homo sapiens with 10 samples.

How the data were processed

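HCT116 cells, an established human colorectal carcinoma line, were profiled by crosslinking and immunoprecipitation followed by sequencing (CLIP-seq), an assay that recovers RNA fragments crosslinked to a chosen protein. Per the labels' protocols, cells were labelled with 200 µM 4-thiouridine, a photoreactive uridine analogue, for 8 h and were crosslinked with 0.2 J/cm2 of UV light at 365 nm. Lysates were treated with RNase I at 0.5 U/µl, and 10 mg of lysate protein entered each immunoprecipitation. A size-matched input library holds RNA bound by any protein that runs at about the size of the target on a gel, and serves as the background. The series labels describe 10 samples in 8 groups. RBMX CLIP and RBMX size-matched input had 2 samples each. The other 6 groups had 1 sample each: RBMX CLIP from size-exclusion chromatography fraction 6 and from fraction 20, and CLIP of ALYREF, V5-tagged FUBP1, V5-tagged FUBP3 and PUM1. Samples were grouped by their titles. Peak lists were analysed for RBMX replicates 1 and 2 (4 libraries), and the remaining 6 samples were not analysed here.

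Per the submitters' processing notes, TopHat2 (version 2.0.8) and Picard were used with the hg19 genome build. The peak caller and its settings are not given in the sources used here. Each deposited list came from 1 CLIP library set against its own input library, per the peak names in the lists, and replicates were not pooled. Lists were assigned to replicates per the labels' descriptions. The deposited lists give, for each peak, a position, a score, a fold enrichment (a ratio of CLIP to expected coverage), a −log10 p-value, a −log10 q-value and a summit position. They give no strand. The deposited score was the whole part of 10 times the −log10 q-value in 100% of peaks of both lists. The highest q-value was 0.0477 in the list of replicate 1 and 0.0455 in that of replicate 2, as converted from the deposited −log10 values. All fold enrichments and p-values of peaks are the authors' values.

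The deposited fold enrichment and −log10 p-value of each peak were solved together for the number of CLIP reads at the summit and the number expected from the input. The relations were fold = (reads + 1)/(expected + 1) and p = the Poisson probability of more than the observed reads. Whole read numbers up to 1000 were tried, with a tolerance of 0.0001 on the −log10 p-value. All peaks of both lists (100%) had a solution, and 0 peaks had another one. On simulated peaks, 100% of 1434 peaks at replicate 1 levels and 100% of 1622 peaks at replicate 2 levels returned the read number they were made with. Expected values moved in steps that gave the worth of 1 input read: 0.181 CLIP reads in replicate 1 and 0.199 in replicate 2. The window behind each expected value was inferred from its relation to these steps. At 56.4% of replicate 1 peaks and 76.8% of replicate 2 peaks it was a whole number of steps. This was read as a window of the minimum peak width, 97 bp and 98 bp. The value matched a 1 kb window at 21.3% and 16.3%, a 10 kb window at 9.93% and 6.33%, and a genome-wide background at 12.4% and 0.543%. Library totals were not given. From the background values and these steps, the depth of replicate 2 relative to replicate 1 was 1.12 for CLIP and 1.02 for input. At peaks that overlapped between the replicates, the median ratio was higher, at 1.40 for CLIP reads and 1.84 for expected values. Because 1 is added to both terms, the deposited fold falls short of the plain ratio most where few input reads were expected.

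Coordinates are given on hg19 and counted from 1. The annotation used here was GENCODE release 29 on GRCh38, another build, so no peak was assigned to a gene, exon or intron and no gene name was given to a region. It served only for the number of protein-coding genes per chromosome, on 22 autosomes and chromosome X. As a check on the builds, 11.2% of replicate 1 summits fell in GRCh38 exons at the deposited coordinates. After moves of 10000 bp to either side this was 10.2% and 9.33%. In replicate 2, 12.6% fell in exons, and 10.3% and 9.27% after the moves. No coordinates were converted between builds.

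Peaks were called shared when they overlapped a peak of the other replicate by at least 1 bp, without regard to strand. Overlaps were computed in Python and counted again with bedtools (version 2.31.1), which gave the same counts of 628 and 634 peaks. Chance overlap came from 1000 seeded draws in which each replicate 2 peak was moved by 500 to 5000 bp in a random direction, with a one-sided permutation p. On simulated lists with 300 planted shared peaks, 301 were found. Each shared peak of replicate 1 was paired with the replicate 2 peak that overlapped it most, so a replicate 2 peak could stand in several pairs. Correlations used two-sided permutation tests with 100000 resamples. Peaks are not independent replicates, so those p-values describe peaks within this pair of lists. Clusters joined peaks with gaps of at most 10 kb, and chance came from 1000 draws with peaks placed at random on the same chromosome. Shares have exact Clopper-Pearson 95% intervals, and fold enrichments have intervals from exact Poisson limits on the CLIP reads. The fold intervals cover counting error of the CLIP reads only, with the expected value held fixed. Reads without molecular identifiers need not be independent molecules. Differences in median fold between mitochondrial and nuclear peaks were tested by two-sided permutation with 100000 resamples. Peaks per chromosome were tested with exact binomial tests against protein-coding gene number, and replicates against each other with Fisher's exact test, both with Benjamini-Hochberg adjustment over 23 chromosomes and a threshold of 0.05.

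The tests, their alternatives and the rule for named regions were fixed before the data were examined. Overlaps and clusters were planned within a strand, but were computed without regard to strand because the lists give none. The rule named the 10 shared regions with the highest lower value of the 2 replicates' fold enrichments, and the 5 clusters with the most peaks in both replicates. Other regions and comparisons were chosen after their values were seen, and are said to be so. Planned tests of annotation classes, gene lists, sequence motifs, splice-site distance and peaks on NORAD need an hg19 annotation or genome and were not run. Alternatives covered the overlap rule, the peak threshold, the chance model, the statistic, the gap of clusters and each replicate alone. Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1, statsmodels 0.14.6 and matplotlib 3.10.9 were used.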

Results

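The series title concerns a protein complex assembled by NORAD, a long noncoding RNA induced by DNA damage. The lists analysed here addressed where in the transcriptome RBMX was crosslinked. RBMX is an RNA-binding protein of the hnRNP family with known roles in splicing. The data were a pair of peak lists from HCT116 cells, each holding the regions enriched in an RBMX CLIP library over its own size-matched input. The list of replicate 1 held 1480 peaks that covered 203964 bp, and that of replicate 2 held 1658 peaks that covered 236532 bp (mean 1569 ± 126 peaks, SD, n = 2). Nothing in the labels says whether the replicates came from separate cultures, so the spread between them may be technical.

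Most peaks were narrow and rested on few reads. The median width was 113 bp in replicate 1 and 122 bp in replicate 2. The median summit held 10 CLIP reads in replicate 1 (interquartile range 5 to 20, range 2 to 88) and 16 in replicate 2 (interquartile range 9 to 29, range 3 to 100). Against these stood medians of 0.542 and 1.19 reads expected from the input. The median fold enrichment was 6.16 in replicate 1 (interquartile range 4.69 to 7.84) and 6.44 in replicate 2 (interquartile range 5.29 to 7.87), with ranges of 2.13 to 22.5 and 2.20 to 21.0. Peaks with at most 5 reads made up 25.5% of replicate 1 (378 peaks) and 5.91% of replicate 2 (98 peaks). The p limit of a list, taken as its lowest −log10 p-value, was 5.07 in replicate 1 and 5.11 in replicate 2. At the genome-wide background (0.0337 and 0.0381 expected), 2 reads pass the limit of replicate 1 but not that of replicate 2. Part of this contrast can thus come from the limits. At 183 peaks of replicate 1 and 9 peaks of replicate 2, the expected value was the genome-wide background, since the local input gave no higher one. When the counting error of the input was added by a binomial test, chosen after the data were seen, 876 peaks of replicate 1 and 1255 of replicate 2 kept the p limit of their list. By construction no peak with at most 6 reads could keep it, even with no input reads counted. The fall in peak number was thus partly fixed in advance.

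The replicates were compared to find the RBMX sites present in both. Of the 1480 peaks of replicate 1, 628 (42.4%, exact 95% interval 39.9 to 45.0) overlapped a replicate 2 peak. Of the 1658 peaks of replicate 2, 634 (38.2%, exact 95% interval 35.9 to 40.6) overlapped a replicate 1 peak. When replicate 2 peaks were moved within their neighbourhood, 43.7 ± 5.38 peaks of replicate 1 overlapped (SD of 1000 draws, highest 59), so that the observed number was 14.4 times the chance number (permutation p = 0.001, the smallest that 1000 draws can give). For replicate 2 the chance number was 47.0 ± 5.42 with a highest value of 64, and the ratio was 13.5 (permutation p = 0.001). The moves took no account of exons or transcript ends, so the chance value does not hold exon position or expression in full. The ratio depended on the chance model and the overlap rule. With moves of 5000 to 50000 bp it was 183 for replicate 1 and 202 for replicate 2, and with a reciprocal overlap of at least 50% it was 40.5 and 39.6 (permutation p = 0.0099, the smallest that 100 draws can give).

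The shared share rose with the number of reads at the summit. In replicate 1 it was 7.41% among peaks with 2 to 5 reads (28 of 378, exact 95% interval 4.98 to 10.5) and 83.1% among those with 25 or more (236 of 284, interval 78.2 to 87.3). In replicate 2 the corresponding shares were 4.08% (4 of 98, interval 1.12 to 10.1) and 69.1% (363 of 525, interval 65.0 to 73.1). Shared peaks of replicate 1 had a median of 19 reads and those found in that list alone a median of 7. In replicate 2 these medians were 27.5 and 11. The median fold enrichment differed less, at 6.79 for shared peaks and 5.63 for the others in replicate 1, and at 6.46 and 6.43 in replicate 2. These splits by reads were chosen after the data were seen.

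**Figure D1:**
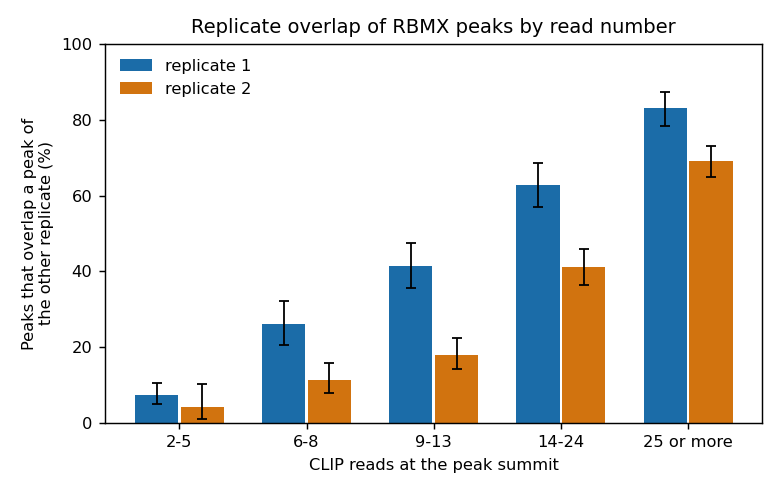
Share of RBMX peaks (percent) that overlapped a peak of the other replicate, by the number of CLIP reads at the summit, for replicate 1 and replicate 2; bars are shares and error bars exact 95% intervals. The share rises from 7.41% to 83.1% in replicate 1 and from 4.08% to 69.1% in replicate 2.

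Over the 628 pairs of shared peaks, summits lay a median of 12 bp apart (interquartile range 3 to 33 bp), and 293 pairs (46.7%) had summits within 10 bp. The fold enrichments of the replicates correlated across these pairs with a Spearman rho of 0.480 and a Pearson r of 0.514 on log2 values. The reads at the summit correlated with a rho of 0.885 and an r of 0.888 on log2 values, and the expected values from the inputs with a rho of 0.910. With reads divided by the expected value and nothing added, the fold correlated with a rho of 0.744. The expected value is a term of either fold and, through the p limit, sets which folds can be listed. Part of the fold correlations can thus come from the inputs. Each permutation p was 1e-05, the smallest that 100000 resamples can give, raw and adjusted over the 8 correlations computed. The correlation was across peaks, and peaks are not independent replicates. Some replicate 2 peaks, mitochondrial ones among them, stood in several pairs. Without mitochondrial peaks the fold rho was 0.425 over 605 pairs.

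**Figure D2:**
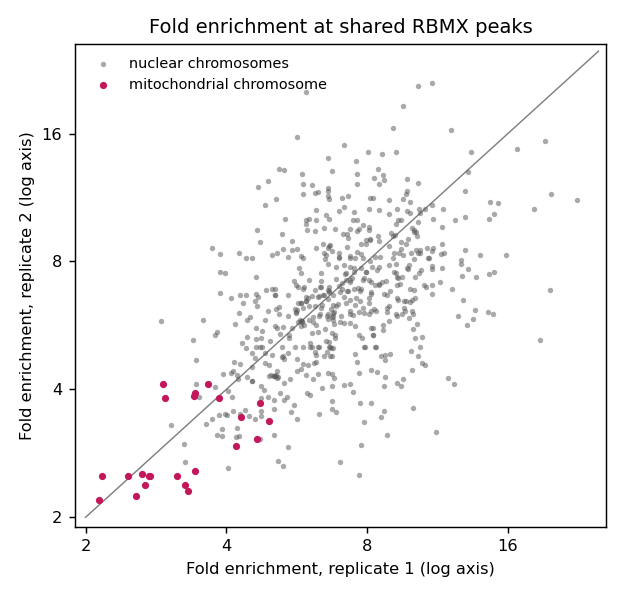
Fold enrichment of each pair of shared RBMX peaks in replicate 1 (horizontal, log axis) and replicate 2 (vertical, log axis), with nuclear chromosomes in grey and the mitochondrial chromosome in magenta; the line marks equal values. Fold enrichments of the 628 pairs correlate with a Spearman rho of 0.480, and mitochondrial pairs lie at the low end in both replicates.

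The 10 shared regions with the highest fold enrichment in their lower replicate lay on chromosomes 2, 3, 4, 6, 11, 12, 17, 19 and 22. Their lower value ran from 11.0 to 15.4, against a median of 5.89 over all 628 shared regions. The region on chromosome 4 at 75480657 to 75480977 led, with 19.2-fold enrichment in replicate 1 (39 reads, 1.08 expected, 95% Poisson interval 13.8 to 26.1) and 15.4-fold in replicate 2 (51 reads, 2.38 expected, interval 11.5 to 20.1). Its summits were at 75480797 and 75480798. The region on chromosome 17 at 22023748 to 22023854 followed, with 16.8-fold and 14.7-fold enrichment from 19 and 18 reads. On chromosome 11, the region at 64889156 to 64889275 was enriched 13.3-fold and 14.5-fold. On chromosome 3, that at 49449205 to 49449365 was enriched 13.1-fold and 13.0-fold. The region on chromosome 2 at 3623204 to 3623308 had values of 12.1 and 16.3, and that on chromosome 22 at 42084726 to 42084863 had 13.0 and 11.7. The region on chromosome 19 at 24010012 to 24010268 was enriched 19.8-fold and 11.5-fold.

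Chromosome 12 held a pair of the named regions. The region at 57039557 to 57039733 had the highest fold enrichment of the replicate 1 list, 22.5 (33 reads, 0.508 expected, interval 15.7 to 31.4). In replicate 2 it had 11.2 (39 reads, 2.58 expected, interval 8.02 to 15.2). It was the only named region whose counting intervals did not overlap between replicates. The intervals overlapped at the other 9 and at 590 of all 628 shared regions. They hold the expected value fixed and leave out the counting error of the input. A lack of overlap therefore does not show a difference beyond counting error. The region at 6862053 to 6862255 was enriched 14.7-fold and 11.0-fold. The region on chromosome 6 at 27799147 to 27799271 was enriched 11.0-fold in replicate 1 (14 reads, interval 6.36 to 18.0), and its 21.0-fold enrichment in replicate 2 (29 reads, interval 14.3 to 29.9) was the highest of that list. With reads divided by the expected value and nothing added, the lower values of the 10 regions ran from 15.1 to 61.7. The region on chromosome 17 then had 98.5 and 61.7, and that on chromosome 6 had 38.7 and 67.8. By this ratio, 1 of the 10 regions stayed among the first 10 and 2 among the first 50.

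RBMX peaks lay closer together than chance placement gave. Clusters of 5 or more peaks held 121 peaks of replicate 1 (8.18%) and 187 of replicate 2 (11.3%), against 1.82% and 1.15% in random placements (permutation p = 0.001 in each, the smallest that 1000 draws can give). These chance shares came almost wholly from mitochondrial peaks, which cluster in any placement on their short chromosome. Without them the shares were 6.47% and 10.3%, against 0 in the random placements. Joined over both replicates, the peaks formed 1794 clusters or lone peaks. Of these, 488 held peaks of both replicates, 626 held peaks of replicate 1 alone and 680 held peaks of replicate 2 alone. At least 5 peaks from each replicate lay in 8 of them. Random placement on the same chromosome takes no account of where genes are transcribed, so the chance value holds neither gene position nor expression.

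The cluster with the most peaks in both replicates spanned the mitochondrial chromosome from 749 to 15869, with 27 peaks in replicate 1 and 19 in replicate 2. The next, on chromosome 6 at 74227199 to 74229744, held 7 peaks in each replicate, all of them shared. Peaks covered 67.4% of its 2546 bp in replicate 1 and 66.0% in replicate 2, with median fold enrichments of 5.57 and 4.38. The cluster on chromosome 11 at 65266588 to 65273577 was covered most fully of these 5, at 89.1% and 77.8% of 6990 bp. It held 6 peaks in replicate 1 and 12 in replicate 2, all of them shared, with up to 88 reads at a summit in each replicate. Its median fold enrichments were 4.65 and 3.33. The cluster on chromosome 12 at 6643722 to 6647566 held 6 and 7 peaks, of which 5 were shared in each replicate. That on chromosome 4 at 152020811 to 152025813 held 6 peaks in each replicate, all of them shared, with median fold enrichments of 6.30 and 6.35.

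**Figure D3:**
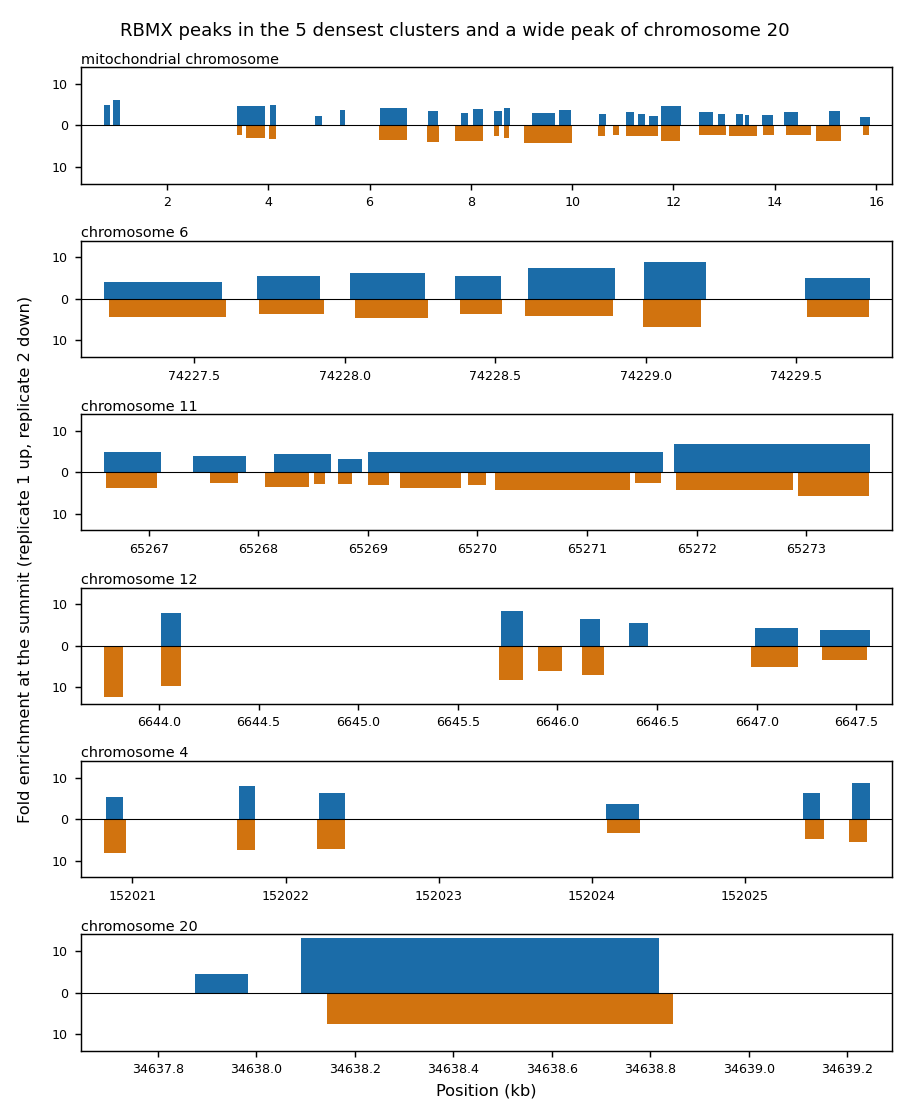
Positions (kb, hg19) of RBMX peaks in the 5 densest clusters and around a wide peak of chromosome 20; each bar spans a peak, and its height is the fold enrichment at the summit, drawn upward for replicate 1 and downward for replicate 2. The chromosome 11 cluster is covered at 89.1% and 77.8% of its length, and the chromosome 20 peak spans 727 bp and 702 bp.

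Nuclear peaks of 500 bp or more numbered 6 in replicate 1 and 5 in replicate 2, and were looked at after the data were seen. The one with the highest fold enrichment in each list was the same region of chromosome 20. It spanned 34638090 to 34638816 in replicate 1, with 13.1-fold enrichment (32 reads, 1.51 expected, 95% Poisson interval 9.11 to 18.4). In replicate 2 it spanned 34638144 to 34638845, with 7.69-fold enrichment (25 reads, 2.38 expected, interval 5.08 to 11.2). It ranked 29 of 1480 and 451 of 1658 peaks by fold enrichment. In replicate 1 the other wide peaks were 4 in the chromosome 11 cluster and 1 on chromosome 6 at 34212700 to 34213965, a 1266 bp peak with 6.86-fold enrichment. In replicate 2 the other 4 all lay in the chromosome 11 cluster.

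Mitochondrial peaks had low fold enrichment on many reads. The 27 peaks of replicate 1 had a median fold enrichment of 3.31 and the 19 of replicate 2 one of 2.57, against 6.23 and 6.44 for nuclear peaks. The differences of −2.93 and −3.88 each had a permutation p of 1e-05, the smallest that 100000 resamples can give. With reads divided by the expected value and nothing added, the differences were −18.7 (permutation p = 0.0284) and −10.5 (permutation p = 0.0121). The p limit of each list keeps out low folds where few reads are expected, by either ratio. Median expected values at nuclear peaks were 0.508 and 1.19, so part of these differences was fixed in advance. Summits of mitochondrial peaks held medians of 57 and 80 reads, against 10 and 16 at nuclear peaks. At mitochondrial peaks, medians of 18.4 and 25.8 reads were expected from the inputs. Of the mitochondrial peaks, 23 of 27 were shared in replicate 1 (85.2%, exact 95% interval 66.3 to 95.8) and 18 of 19 in replicate 2 (94.7%, interval 74.0 to 99.9). The nuclear shares were 41.6% (interval 39.1 to 44.2) and 37.6% (interval 35.2 to 40.0). Nuclear peaks within the mitochondrial range of expected values were shared at 78.8% (164 of 208) and 100% (13 of 13). On the short mitochondrial chromosome, 12.8 and 12.4 peaks overlapped on average when replicate 2 peaks were moved at random. This comparison was chosen after the data were seen.

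Across 23 chromosomes, the mean number of RBMX peaks of the replicates correlated with the number of protein-coding genes (Pearson r = 0.944, Spearman rho = 0.941, permutation p = 1e-05 for each, raw and adjusted over 5 settings). Without chromosomes 1 and 19, the farthest from the median gene number, r was 0.935. With shared peaks only, r was 0.872 and rho 0.886. There were 7.28 peaks per 100 genes in replicate 1 and 8.25 in replicate 2. Chromosome 12 had 9.27 and 11.9 peaks per 100 genes, and chromosome 14 had 4.89 in each. By exact binomial tests with Benjamini-Hochberg adjustment, 0 chromosomes departed from the gene number in replicate 1 (3 at an unadjusted p under 0.05). In replicate 2, 6 did so: chromosomes 6, 12 and 17 held more peaks than their gene number gave, and chromosomes 13, 14 and 21 held fewer. With each cluster counted once, 0 chromosomes departed in either replicate. Fisher's exact test found 0 chromosomes that differed between replicates after adjustment, and 1 at an unadjusted p under 0.05 (chromosome 13, 25 and 14 peaks, exact p = 0.0362, adjusted p = 0.616). These counts per chromosome were also chosen after the lists were seen.

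**Figure D4:**
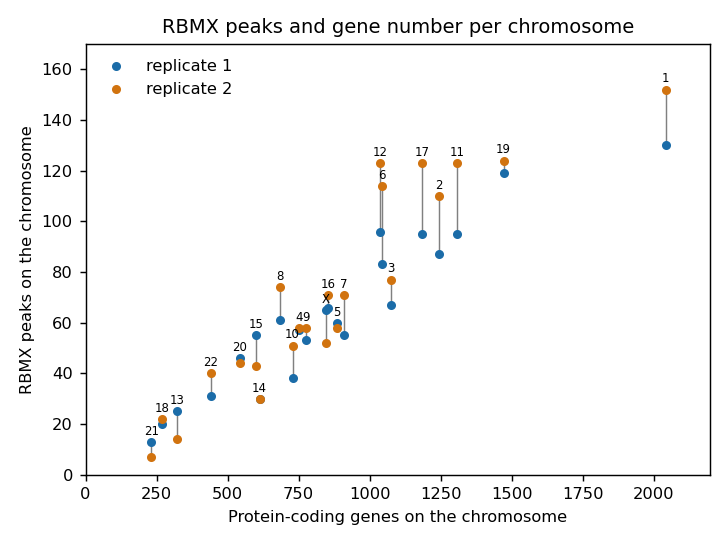
Number of RBMX peaks on each of 23 chromosomes against its number of protein-coding genes, for replicate 1 and replicate 2, with a line joining the replicates of each chromosome. Peak number rises with gene number (Pearson r = 0.944 for the mean of the replicates).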

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

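The overlap of the replicates stayed above chance in all 9 alternatives for each list. The planned ones gave shared shares of 34.6% to 49.0% in replicate 1 and 30.8% to 44.0% in replicate 2. Chosen after the data were seen were the settings without minimum-width, mitochondrial or low-read peaks, the binomial test with input counting error, the plain ratio of reads to expected value, the single replicates of clustering, and all settings of the mitochondrial and chromosome comparisons. With at least 10 reads required, 64.5% and 42.0% of peaks were shared. When the counting error of the input was added by a binomial test, 876 of 1480 peaks of replicate 1 kept the p limit of that list, and 1255 of 1658 peaks of replicate 2 did. By construction this test weighs few input reads as less certain, and no peak with at most 6 reads can pass it. The fold correlation ranged from 0.425 without mitochondrial peaks to 0.744 with the plain ratio. The same ratio moved the lower value of 9 of the 10 named regions by at least the SD between their replicates' fold enrichments. Clustering was 4.11% with a gap of 1 kb and 13.1% with 50 kb, and 8.18% and 11.3% in the single replicates. The mitochondrial difference ran from −3.88 to −2.93 and the chromosome correlation from 0.927 to 0.949 with 1 replicate left out. With shared peaks only, the chromosome correlation was 0.872. With the plain ratio the mitochondrial difference was −14.6 (larger permutation p of the replicates 0.0284). No paired analysis was possible because each deposited list already sets 1 CLIP library against its own input. The planned tests within a strand could not be run, since the lists give none, so all overlaps and clusters ignored strand. For want of an hg19 annotation used here, the chance model within genes was not run. Nor were the alternatives for annotation, gene, motif and splice-site tests. Whether depth accounts for peaks of few reads found in 1 list alone was not tested, and such a site is not shown to be absent from the other replicate.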

Other observations

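The regions here, the tests of minimum-width peaks, the redraws with lowered reads or the depth ratio, the restriction to 10 or more expected reads and the count of matched mitochondrial peaks were chosen after the data were seen; the redraw at full reads and the comparison of mitochondrial with nuclear peaks in 1 range of expected values were set out before their results. Some clusters were uneven between replicates. The cluster on chromosome 11 at 65191146 to 65202895, at lower coordinates than the densely covered one, held 9 peaks in replicate 1 and 3 in replicate 2, with up to 61 and 48 reads at a summit. On chromosome 2 at 198352519 to 198366007 there was 1 peak in replicate 1 and 7 in replicate 2. On chromosome 7 at 156775095 to 156776283 replicate 2 alone had peaks, 6 of them over 71.2% of 1189 bp, each with at most 14 reads. On chromosome 1 at 149804249 to 149832699 the replicates had 5 and 6 peaks, with highest fold enrichments of 8.13 and 20.0 from at most 13 and 27 reads. These differences were not tested.

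Peaks found in a single list were ranked by q-value with chromosome Y left out. That with the lowest q-value in replicate 1 lay on chromosome 2 at 27615746 to 27615877, with 20.6-fold enrichment from 42 reads. In replicate 2 it lay on chromosome 1 at 149812581 to 149812734, with 18.0-fold enrichment from 24 reads. Such peaks led to the question whether counting error accounts for sites missing from the other list. Peaks of replicate 1 with 25 or more reads were redrawn with Poisson error at the levels of replicate 2, and 98.4% passed its p limit (95% of draws 97.2 to 99.6), against an observed shared share of 83.1%. In the other direction, 98.0% passed against 69.1%. With the plain depth ratio of the libraries in place of the ratio at shared peaks, 99.3% and 97.4% passed. Peaks selected for high counts overstate their level. Allowing for this with the fall-off of read numbers in each list, which lowers the level to 93.0% and 93.5% of the reads, 95.9% and 95.4% passed, still above the observed intervals of 78.2 to 87.3 and 65.0 to 73.1. Lowering all reads to 70%, an arbitrary value, gave 85.1%, within the observed interval of replicate 1, and 83.9%, above that of replicate 2. At the level the read numbers give, Poisson error of independent reads thus did not account for all peaks of 25 or more reads in a single list. If reads were amplified copies of fewer molecules, the error would exceed the redrawn one. This stays open, and peaks of fewer reads were not tested in this way. Peaks of the minimum width made up 43.4% of the peaks found in replicate 1 alone (370 of 852, exact 95% interval 40.1 to 46.8) and 21.1% of those in replicate 2 alone (216 of 1024, interval 18.6 to 23.7). They were thus not the whole source of peaks in a single list; no biological explanation was tested.

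Peaks of the minimum width, 97 bp in replicate 1 and 98 bp in replicate 2, made up 29.3% and 14.8% of the lists and were shared less often. Low read number did not account for this in full: at equal read number, 64 were shared where 75.8 were expected in replicate 1 (ratio 0.844, permutation p = 0.0198), and 30 where 40.3 were expected in replicate 2 (ratio 0.744, permutation p = 0.0166). A candidate explanation that stays open is that some are stacks of reads with 1 start position, as amplified copies of a fragment would be. Among peaks with 9 or more reads the ratio was 0.790 in replicate 1 (permutation p = 0.0236) and 0.594 in replicate 2 (permutation p = 0.0016), which any cause of the deficit would give and which does not single out stacking. With 14 to 24 reads there was no deficit in replicate 1 (63.6% of minimum-width and 62.8% of wider peaks shared), against 17.2% and 42.8% in replicate 2. In replicate 2 there was no clear deficit at 2 to 5 reads (5.97% and 0%) or at 6 to 8 reads (11.1% and 11.4%). Start positions were not analysed here.

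The low fold enrichment of mitochondrial peaks was set against nuclear peaks in the same range of expected values. The median fold difference, mitochondrial minus nuclear, was −2.11 in replicate 1 (208 nuclear peaks, permutation p = 1e-05, the smallest possible). In replicate 2 the medians were 2.57 and 3.57 (13 nuclear peaks, permutation p = 0.0484). Among peaks with 10 or more expected reads the differences were −1.06 (24 mitochondrial and 16 nuclear peaks, permutation p = 0.0017) and −0.931 (19 and 63 peaks, permutation p = 6e-05). The read depth of the mitochondrial chromosome stays open all the same, because the expected values were not equal in either comparison. Within the range their medians were 18.4 at mitochondrial and 4.70 at nuclear peaks in replicate 1, and 25.8 and 18.7 in replicate 2. With 10 or more expected reads they were 19.3 and 11.8, and 25.8 and 12.5. The expected value lay above that of every nuclear peak at 16 of 27 mitochondrial peaks in replicate 1 and at 17 of 19 in replicate 2. A nuclear peak within 10% of the expected value existed for 15 and 4 mitochondrial peaks. Depth and a lower crosslinking of RBMX to mitochondrial RNA therefore cannot be told apart in these lists, and no biological explanation was tested.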
